A study of Mus musculus with 15 samples.

How the data were processed

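The data are oligonucleotide array values for RNA of A.E7 cells under 5 treatments (mock; anti-TCR alone; anti-TCR with cyclosporin A; anti-TCR with a PKC inhibitor; anti-TCR with rapamycin, PD98059 and SB203580), pooled from 2, 4 and 6 h and read on chip types A, B and C. The array intensity values were used as deposited; they are linear, none is below 0, and the 2% trimmed means of the 5 arrays of a chip type lie within 0.232% (A), 0.242% (B) and 0.153% (C) of each other, so each array had been scaled to a common level. How the scaling was done, and with which software, is not given in the sources used here, and the tables hold no detection calls. Groups were taken from the array titles and labels. The chip types hold 12422, 12411 and 11868 probe sets, 36701 in all. Of these, 29131 carry 1 gene symbol, 724 carry several and 6846 carry none; the last 2 kinds were left out of gene counts and are described separately. Matching the annotation's gene identifiers to a current gene table (29044 matched) changed 0 symbols. For 8897 probe sets the name ends in r, i, f, s or g before "at", which marks a probe set that shares sequence or breaks a selection rule; the text marks named genes read on them.

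Array medians for mock, anti-TCR, CSA, PKCi and Combo were 53.6, 50.7, 52.3, 51.25 and 46.95 on chip type A, 68.7, 68, 69.9, 70.2 and 70.8 on B, and 56.9, 54.2, 55.15, 54.1 and 55.05 on C. The median of all values of a chip type served as the floor (51.1, 69.5 and 55); lower values were raised to it before log2 was taken. A gene is 1 symbol, read from its probe set with the highest mean over the 5 treatments, which gave 15964 genes. It entered a comparison only if the brighter value reached 4 times the floor (204.4, 278 and 220), and a change is a ratio of at least 2-fold. The 4 comparisons are anti-TCR against mock and each inhibitor arm against anti-TCR alone. No paired analysis and no test was possible because there is 1 array per treatment and chip type and the chip types read different probe sets of the same pools. These choices, the gene lists and the naming rule were fixed before the data were examined.

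Technical spread was the SD of the difference in log2 ratio between probe sets of the same gene on different chip types, divided by the square root of 2. Over 847, 786, 865 and 838 pairs it was 0.76 for anti-TCR against mock, 0.48 for CSA, 0.71 for PKCi and 0.55 for Combo. Because probe sets of 1 gene also differ in what they bind, a second spread, which includes real differences between the treatments, was taken from the PKCi and Combo arrays (SD 0.65 over 5606 genes), after the data were seen. Also then, the count of changed genes was simulated with the spread of each comparison alone, and the loss of induction with that of anti-TCR against mock. With each, 100 simulations drew arrays with no difference between treatments, or with no inhibitor effect on the induced genes, and were counted like the data. Genes were also chosen on 1 probe set and read on another probe set on another chip type. The share of induction left is the log2 ratio of inhibitor to mock divided by that of anti-TCR to mock, with an order-statistic 95% interval for its median; with mock below the floor it depends on the floor and is a lower bound while the inhibitor value lies above it; percentages carry Wilson intervals.

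The median log2 ratio of the measured members of each of 25 fixed lists was placed among 10000 random lists of the same size matched on mean level (20 classes). The lists were immediate early transcription factors, cytokines and chemokines, activation receptors, anergy or negative regulation, the calcineurin and NFAT pathway, NF-kB genes, MAP kinase phosphatases and Sprouty genes, sterol and fatty acid synthesis, glycolysis, Atf4 targets, nucleolar ribosome biogenesis, DNA replication, mitosis, quiescence, the TCR complex, interferon response, heat shock, apoptosis, effector genes, housekeeping genes, ribosomal proteins, and markers of B cells, of macrophages and dendritic cells, of CD8 T and NK cells, and of erythroid cells and neutrophils. Genes named in the text are the 10 highest and 10 lowest of each comparison among those whose further bright probe sets moved the same way, the 10 largest inductions of the class lowered by CSA alone, the 2 highest and 2 lowest of a list, and the Egr family; Ifng with CSA, Il2 and Cd8a, and examples marked so in the text, were chosen after their values were seen.

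The gene-level steps were tested on simulated data with 200 planted genes among 15964: 84% of 3-fold and 98% of 8-fold changes were called, and 14.5% of the 5534 unchanged genes that reached 4 times the floor. Alternatives tried were quantile normalization, trimmed mean scaling, median scaling, 0.5 times the floor, 2 times the floor, the mean of a gene's probe sets, 8 times the floor as minimum, and loss counted as under 50% of the log2 induction left. Leaving out suffixed probe sets and requiring 2 or more probe sets to be 2-fold apart were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.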

Results

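Expression was measured in A.E7 cells, a mouse CD4 T helper clone, that were mock treated or stimulated through the T cell receptor (TCR). Stimulated cells received anti-TCR alone, the treatment that the array titles call anergic, or anti-TCR with 1 of 3 inhibitor treatments. CSA was cyclosporin A, which blocks the phosphatase calcineurin. PKCi was an inhibitor of protein kinase C that the labels do not name further. Combo was rapamycin, which blocks mTOR, together with PD98059, which blocks the kinase MEK, and SB203580, which blocks the kinase p38. RNA from 2, 4 and 6 h was pooled for each treatment, and each pool was read on 3 chip types (A, B and C) that hold different probe sets, which gave 15 arrays. There was 1 array per treatment and chip type, so no difference has a replicate check, an SD over cultures or a test, and the number of arrays limits the precision. A gene is said to have risen or fallen when its values lay at least 2-fold apart and the brighter one reached 4 times the floor, and "at least" marks a fold whose dimmer value lay at or below the floor. Between 17.4% and 23.0% of an array's probe sets reached 4 times the floor. Over 3336 differences between probe sets of the same gene on different chip types, the log2 ratio had a technical SD of 0.64. These differences are pooled over the 4 comparisons, so 1 pair of probe sets can count once in each. The SD covers array and probe differences and not cultures.

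The first comparison, anti-TCR alone against mock, asks which genes respond to engagement of the receptor. Of the 10 largest rises, 5 were transcription factors of the Egr and Nr4a families. Egr2 rose from 43.8 to 3325 (at least 65.1-fold) and Egr3 from 121 to 4354 (35.9-fold); both are receptor-induced zinc finger factors linked to T cell anergy. The orphan nuclear receptors Nr4a3, Nr4a2 and Nr4a1 rose 66.7-fold, at least 49.6-fold and 46.9-fold. Xcl1 and Ccl1, chemokines of activated T cells, rose at least 48.4-fold and 38.8-fold, Spry1, a feedback inhibitor of receptor signalling, at least 49.3-fold, the histone demethylase Kdm6b at least 58.8-fold and Rhbdf2 at least 53.7-fold. In the other direction Synrg fell at least 19.1-fold, the sialyltransferase St8sia4 12.7-fold, Nxpe3 10.7-fold, Ctla2b 8.79-fold, Card6 8.78-fold and Acsbg1 7.87-fold. Plk3 (18.1-fold lower), Acp5 (10.8-fold lower), the PI3 kinase inhibitor Pik3ip1 (7.68-fold lower) and Mxd4, a MAX partner that opposes Myc (11.5-fold lower; its 3 bright probe sets lay between -3.52 and -1.54), were read on probe sets whose suffix marks a broken or shared probe design. A second bright probe set gave a smaller log2 ratio for Nr4a1 (0.22 against 5.55), Nr4a3 (2.60 against 6.06) and Ccl1 (2.50 against 5.28), and a similar one for Egr3 (4.71 against 5.17) and Nr4a2 (4.58 against 5.63).

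Of 5803 genes measured, 659 (11.4%) rose and 808 (13.9%) fell, 228 and 153 of them at least 4-fold. The excess of falls depends on the scaling: 44.9% of the changed genes were higher, and 49.7% with median scaling. Arrays with no difference, simulated 100 times with noise taken from probe sets of the same gene, gave 786 genes at least 2-fold apart on average (705 to 858) and 72.8 at least 4-fold apart (51 to 95), against sums of 1467 and 381. A second estimate, added after the data were seen, came from the PKCi and Combo arrays, the pair with the fewest genes 2-fold apart (497). It includes real differences between those treatments, so it is an upper limit for the noise of that pair and not of other pairs. This estimate gave 631 (549 to 707) and 74.6 (51 to 97). A last estimate, also added later, took the spread of this comparison alone, which is wider. It gave 1251 (1165 to 1316) and 148 (126 to 172). This spread can hold real response, since probe sets of a gene differ in what they bind. It was 0.76 here, 0.71 for PKCi, 0.55 for Combo and 0.48 for CSA. The genes 2-fold apart ran in the same order (1467, 1392, 754 and 555). The last estimate may therefore be too high for noise and cannot set how many calls are real. By each estimate many single calls near 2-fold may be noise. Among the genes that rose, 172 had a further bright probe set, and all bright probe sets of 145 (84.3%) pointed up; among those that fell the count was 115 of 141 (81.6%).

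**Figure D1:**
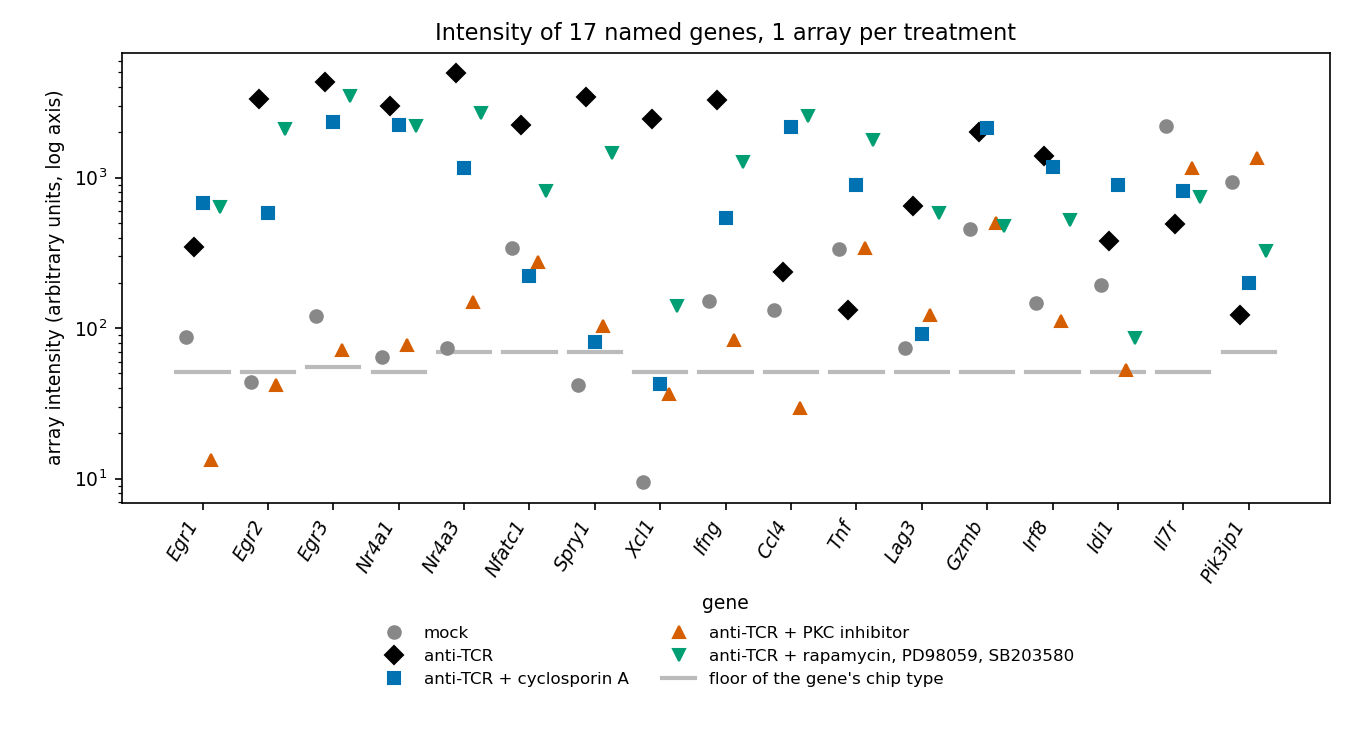
Array intensity (arbitrary units, log axis) of 17 named genes, with 1 point per treatment and no error bars because each treatment has 1 array; grey lines mark the floor of the chip type. Egr2 lies at 3325 with anti-TCR alone, 582 with CSA, 41.7 with PKCi and 2116 with Combo, whereas Tnf and Ccl4 lie higher with CSA and Combo than with anti-TCR alone.

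Immediate early transcription factors rose as a group. Of 21 measured, 16 rose and 0 fell (median log2 ratio 2.95), and the median lay above all of 10000 random lists matched on mean expression (percentile 100), a description of these arrays and not a test. Egr1 rose 3.98-fold, from 86.9 to 346. Egr4, read on an r-suffixed probe set, was 442 and 497, while Jund (log2 ratio -0.30) and Klf6 (-0.42) did not pass the size rule. Of 14 measured cytokine genes 11 rose and 1 fell (median 4.36, percentile 100). Ltb, which encodes lymphotoxin beta, was level (2723 and 2737), and Tnf fell 2.52-fold, from 334.5 to 133. Il2, a T cell growth factor gene that was looked up outside the naming rule, read 1.3 with mock and 2.6 with anti-TCR, both below the floor. A probe set that does not work would also give this, so these values do not show whether Il2 was expressed. Activation receptors rose in 5 of 12 cases and fell in 0 (median 0.72, percentile 99.86), with the inhibitory receptor Lag3 8.68-fold higher and Tnfrsf9 (4-1BB) at least 6.87-fold higher, against 0.26 for Tnfrsf18 and -0.82 for Ctla4 on the log2 scale.

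Of 26 measured genes linked to T cell anergy or negative regulation, 11 rose and 2 fell (median 0.75, percentile 100). Egr2 and Egr3 belong to this list too; the 2 that fell were Nedd4 (4.46-fold), a ubiquitin ligase, and Dgka (2.42-fold), the kinase that removes diacylglycerol. The calcineurin and NFAT list moved the other way, with 2 genes up and 5 down among 14 (median -0.72, percentile 0.35): Nfatc1 rose 6.54-fold and Ppp3r1, the regulatory subunit of calcineurin, 2.88-fold, while Nfatc2 fell 2.72-fold and Nfatc3 2.57-fold. The 3 bright probe sets of Nfatc1 ranged from 1.69 to 3.84, and the second one of Ppp3r1 gave 0.09. Among 14 NF-kB family members and targets, 6 rose and 1 fell (median 0.89, percentile 99.96), led by Bcl3 (14.6-fold) and Nfkbiz (at least 7.39-fold), with Traf1 2.92-fold lower and Birc2 at -0.88. MAP kinase phosphatases and Sprouty genes rose in 5 of 7 cases and fell in 1 (median 1.23, percentile 99.82). The ERK phosphatase Dusp6 rose at least 12.4-fold (log2 ratio 3.63, and 1.69 on a second probe set), Dusp7 fell 4.42-fold, and Dusp14 (0.42) did not pass.

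Metabolic and growth genes rose in several groups. Targets of the amino acid response factor Atf4 rose in 9 of 13 cases and fell in 0 (median 1.42, percentile 100), among them the amino acid transporter Slc7a5 (4.76-fold) and, on an i-suffixed probe set, Sesn2 (at least 8.36-fold), with Cebpb at -0.13 and, on an r-suffixed probe set, Wars at -0.25. Of 12 glycolysis genes 5 rose and 2 fell (median 0.83, percentile 99.91). The enzymes Pgam1 and, on a g-suffixed probe set, Pfkp rose 5.42-fold and 4.58-fold; Pdk1, which restrains pyruvate oxidation, fell 2.83-fold and the oxygen sensor Egln3 2.37-fold (-0.14 on a second probe set). Nucleolar ribosome biogenesis genes rose in 7 of 19 cases and fell in 0 (median 0.80, percentile 99.99), with Rrs1 5.49-fold and fibrillarin (Fbl) 3.12-fold higher, and Nolc1 (0.20) and Npm1 (0.17) short of the size rule. Of 15 sterol and fatty acid synthesis genes 3 rose and 1 fell (median 0.44, percentile 97.61). Insig1, a sensor of the sterol pathway, rose 4.26-fold and Cyp51 2.49-fold, whereas Scd2 fell 2.62-fold and Nsdhl read -0.90, both on f-suffixed probe sets. Heat shock genes rose in 4 of 12 cases and fell in 0 (median 0.65, percentile 99.51), with Hspa1b 9.24-fold and Hspa1a at least 7.29-fold higher and Dnaja1 (0.18) and Hspe1 (0.14) level.

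Genes of resting and recirculating T cells fell in 5 of 12 cases and rose in 1 (median -0.36, percentile 10.485). The IL-7 receptor gene Il7r fell 4.50-fold, and Foxp1 rose 2.05-fold on an i-suffixed probe set whose 2 further probe sets reached down to 0.41; Tob1 read 0.84. Of 17 genes of the receptor complex and its proximal signalling 2 rose and 4 fell (median -0.06, percentile 51.075). The adaptor Lcp2 (SLP-76) rose 4.42-fold and the kinase Fyn 2.68-fold, while the adaptor Pag1 fell 3.33-fold and Vav1 2.17-fold. Interferon response genes gave 1 up and 3 down of 7 (median -0.69, percentile 5.01); Irf8 rose 9.50-fold, and Psmb9 and Tap1, which serve antigen processing, fell 3.82-fold and 2.52-fold, with Gbp3 at 0.29. Of 7 effector genes 2 rose and 1 fell (median 0.86, percentile 99.355, range over the alternatives tried 0.28 to 0.89). Granzyme B (Gzmb) rose 4.44-fold and Il18rap 2.14-fold, Stat4 fell 3.78-fold and Il18r1 read -0.93. Apoptosis regulators gave 1 up and 1 down of 9 (median -0.06, percentile 53.19), namely Fasl (3.04-fold higher) and Tnfsf10 (2.38-fold lower), with Cflar at 0.85 and Mcl1 at -0.98 (f-suffixed). Of 11 replication genes 3 rose and 0 fell (median 0.24, percentile 89.85): cyclin D2 (Ccnd2) rose 6.18-fold and Cdc45 2.13-fold on an r-suffixed probe set, against -0.19 for Cdk4 and -0.11 for Ccne2 (r-suffixed). Of the mitosis list only 3 genes were bright, Mad2l1 (3.97-fold lower), Cdc20 (1.99-fold higher, just under the limit) and Plk1 (-0.56, f-suffixed), which gave 0 up and 1 down (median -0.56, percentile 37.755).

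The reference lists are housekeeping and ribosomal protein genes. Of 9 housekeeping genes 1 rose, Tubb5 (4.49-fold, on an f-suffixed probe set; lowest of 3 probe sets 0.85), and 0 fell (median 0.24, percentile 87.425), with Ywhaz at 0.52, Actb at -0.29 (f-suffixed) and Hprt at -0.56. Of 26 cytosolic ribosomal protein genes 1 rose, Rpl41 (log2 ratio 1.07, f-suffixed), and 0 fell (median -0.30, percentile 7.015); Rps13 read 0.99, Rps28 -0.66 and Rps24 -0.70 (r-suffixed). Markers of other cell types were mostly dark. Of 14 B cell and antigen presentation markers on the arrays 0 were measured, and of 11 erythroid and neutrophil markers 0. Of 18 macrophage and dendritic cell markers 2 were measured, Ctss, which fell 3.07-fold, and Cd14 (-0.42), which gave 0 up and 1 down (median -1.02). Of 8 CD8 T and NK cell markers on the arrays 4 were measured, of which 0 rose and 3 fell (median -1.27, percentile 0.34): Klre1 2.72-fold, Klrd1 2.55-fold and Klrk1 2.28-fold, with Klrc1 at 0.12. Klrd1 was bright with mock (4063), while Cd8a read 4.7 with mock and 7.5 with anti-TCR, below the floor, which a probe set that does not work would also give.

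**Figure D2:**
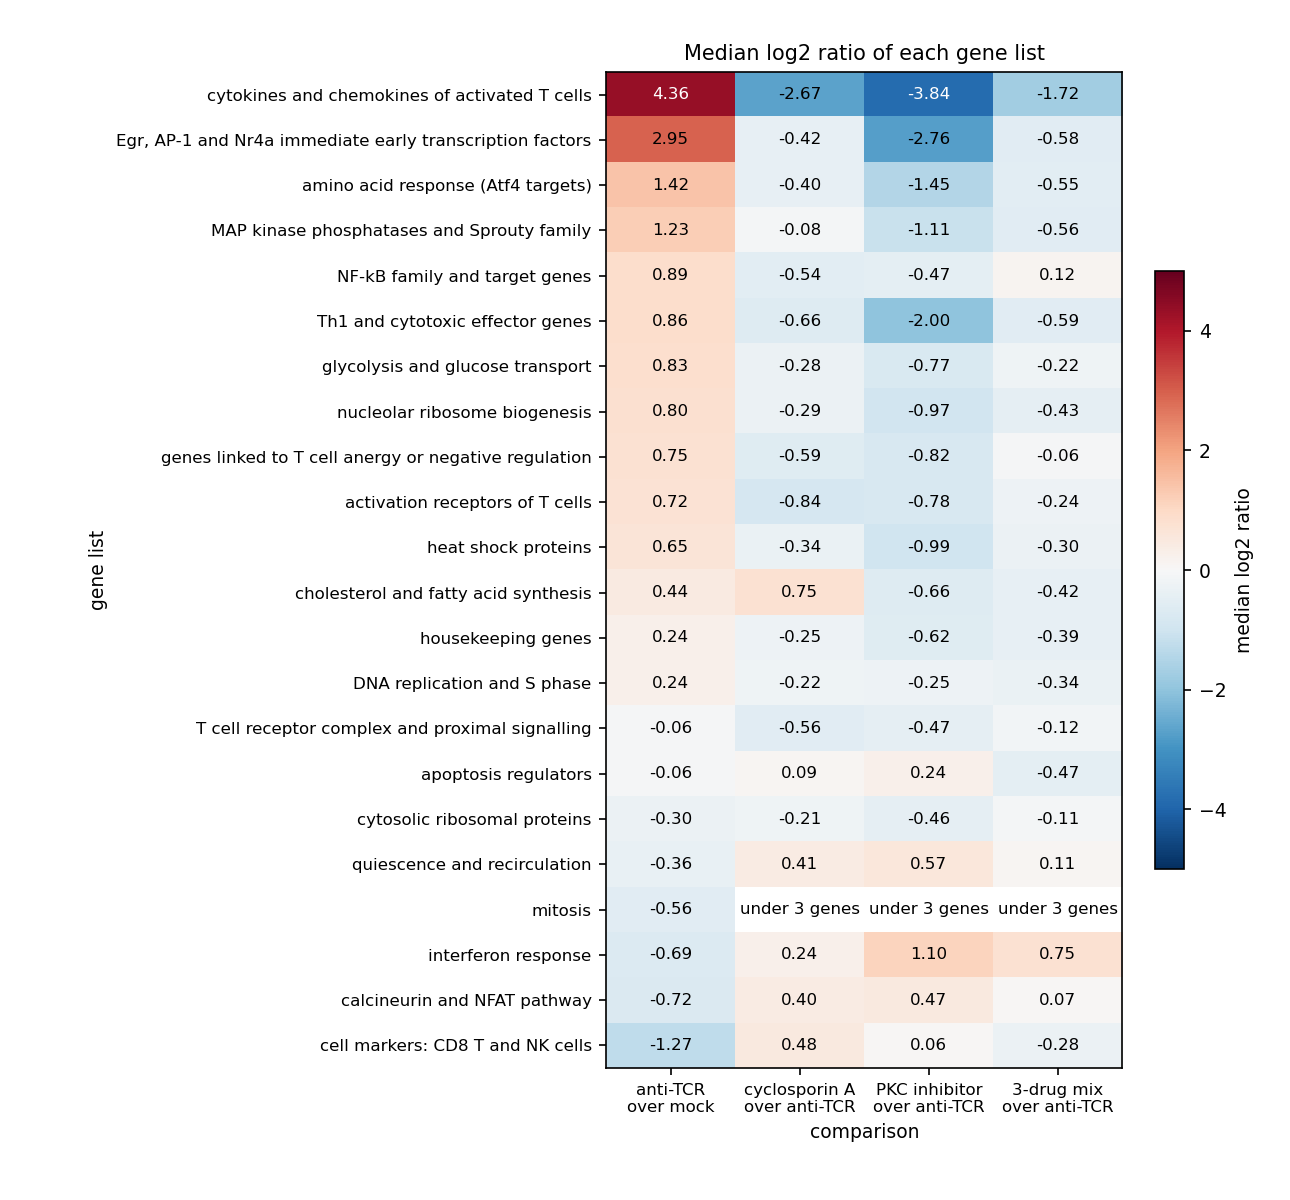
Median log2 ratio of each gene list (vertical axis) in each of the 4 comparisons (horizontal axis), with the value in each cell and colour from blue (lower) to red (higher); medians over under 3 measured genes are not shown. The cytokine list moves from 4.36 with anti-TCR over mock to -2.67, -3.84 and -1.72 with CSA, PKCi and Combo over anti-TCR, and the sterol list is at 0.75 with CSA and at -0.66 and -0.42 with PKCi and Combo. Over the alternatives tried, the sterol median with CSA ranged from 0.14 to 0.77. Housekeeping genes, a reference, are at -0.62 with PKCi and -0.39 with Combo.

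The second comparison, CSA with anti-TCR against anti-TCR alone, asks which of these changes need calcineurin. Chemokine genes and Spry1 fell furthest. Xcl1 and Ccl1 fell at least 48.4-fold and 38.8-fold, to below the floor, and Ifng 6.06-fold, from 3261 to 538. Spry1 fell 42.2-fold, Nr4a2 20.8-fold, the adaptor gene Plek 22.6-fold, the nucleoside transporter gene Slc29a1 17.3-fold, the kinase gene Map3k8 at least 16.1-fold and Ipcef1 at least 15.4-fold; Kif15 (27.9-fold) was read on an f-suffixed probe set, and Rilpl2 fell at least 18.5-fold on its brightest probe set and -0.64 in log2 on the other. The Egr family split. Egr2 fell 5.71-fold to 582, which left at least 58.3% of its log2 induction (its mock value is below the floor), Egr3 read 2359 (log2 ratio -0.88, and -2.24 on a second probe set) and Egr1 675 (0.97), neither past the size rule. Egr4 rose 2.24-fold on its r-suffixed probe set, while its other bright probe set gave -0.01. Nr4a1 kept 92.4% of its induction and the histone demethylase Kdm6b at least 89.8%.

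Ier5l, a member of an immediate early family, rose 22.0-fold with CSA to 5812, with a second probe set at 3.40 on the log2 scale. The chemokine Ccl4 rose 9.16-fold, from 237 to 2171, and Tnf 6.72-fold, from 133 to 892. Synrg rose at least 12.8-fold (log2 ratio 3.68, and 1.67 on a second probe set). The sorting nexin Snx20 rose 7.72-fold, Ctla2b 6.65-fold, the ubiquitin ligase Nedd4 6.52-fold, the G protein regulator Rgs2 5.89-fold, Slc46a3 at least 5.61-fold and, on an i-suffixed probe set, Slco6b1 5.38-fold. Of 5453 genes measured, 264 (4.84%) rose and 291 (5.34%) fell, 29 and 91 of them at least 4-fold. The sum at 2-fold, 555, lies below or inside the ranges of the first 2 noise estimates (705 to 858 and 549 to 707), which are wider than the spread of this comparison; with its own spread, noise gave 282 to 380. The sum at 4-fold, 120, lies above all 3 (at most 95, 97 and 50).

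By list, cytokines fell in 11 of 14 cases and rose in 2 (median -2.67, percentile 0), those 2 being Ccl4 and Tnf. Activation receptors fell in 7 of 14 cases and rose in 2 (median -0.84, percentile 0): Lag3 fell 7.02-fold and Slamf1 6.20-fold, and Cd69 and the adhesion receptor Cd44 rose 2.39-fold and 2.20-fold. Of 25 anergy-linked genes 9 fell and 2 rose (median -0.59, percentile 0). Nfatc1 fell from 2236 to 223, with its 3 bright probe sets between -4.33 and -2.82, and Ndrg1 7.63-fold; the 2 that rose were Nedd4 and Rgs2. In the calcineurin and NFAT list 3 of 14 rose and 1 fell (median 0.40, percentile 99.07). Over the alternatives tried, this median ranged from 0.07 to 0.54. Nfatc2 rose 4.29-fold and Nfatc3 2.41-fold; Nfatc1 fell, and Ppp3r1 read -0.48. Immediate early factors fell in 7 of 21 cases and rose in 2 (median -0.42, percentile 0.02), the second of those 2 being Maff (2.13-fold). NF-kB genes fell in 3 of 13 cases and rose in 0 (median -0.54, percentile 0.04), with Nfkb2 2.32-fold and Nfkbib 2.26-fold lower and Nfkbiz at 0.89. Receptor complex genes fell in 4 of 15 cases and rose in 1 (median -0.56, percentile 0.04): Lcp2 fell 5.65-fold and Cd2 3.49-fold, and Pag1 rose 2.67-fold. In the Sprouty and phosphatase list 2 of 8 rose, Dusp1 (2.67-fold) and Dusp7 (2.59-fold), and 2 fell (median -0.08, percentile 36.47).

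Sterol and fatty acid synthesis genes rose in 6 of 18 cases and fell in 0 (median 0.75, percentile 99.99), with Scd2 3.43-fold higher on an f-suffixed probe set and Msmo1 2.48-fold higher, against -0.99 for Acaca. The size of this median depends on the processing, with a range of 0.14 to 0.77 over the alternatives tried. In the quiescence list 1 of 11 rose and 2 fell (median 0.41, percentile 98.945); Foxo1 rose 3.40-fold, Slfn2 fell 4.22-fold and Foxp1 3.37-fold, the last 2 on i-suffixed probe sets. Atf4 targets fell in 3 of 13 cases and rose in 0 (median -0.40, percentile 1.05), with Slc3a2 2.15-fold and, on an i-suffixed probe set, Sesn2 at least 8.36-fold lower. Cyclin D2 (Ccnd2) fell 5.12-fold. In the effector list 2 of 7 fell and 0 rose (median -0.66, percentile 0.16): Il18rap fell 3.67-fold and Gzma 2.16-fold (s-suffixed), whereas Gzmb, at 2141, kept its induction (104%). Ribosomal protein genes fell in 2 of 26 cases and rose in 0 (median -0.21, percentile 1.83), so reference genes read lower too. Medians of the lists not named here are in the heat map.

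The third comparison, PKCi with anti-TCR against anti-TCR alone, asks which changes need protein kinase C. The strongest anti-TCR-induced genes fell to or near their mock level. Egr2 fell at least 65.1-fold, to 41.7, Egr3 60.5-fold, to 72, Kdm6b at least 58.8-fold, Rhbdf2 at least 53.7-fold, Nr4a1 38.8-fold (second probe set only -0.19) and Nr4a3 33.3-fold (second -2.18, against -5.06), and Egr1 fell at least 6.76-fold. Among cytokines Xcl1 fell at least 48.4-fold, Ccl1 at least 38.8-fold and Ifng 38.8-fold, from 3261 to 84.1, and Spry1 fell 33.2-fold. Mxd4 rose 20.2-fold on an s-suffixed probe set, with its 3 bright probe sets between 2.07 and 4.34. Snx20 rose 15.7-fold, Synrg at least 12.7-fold (log2 ratio 3.67, and 2.49 on a second probe set), C730049O14Rik 12.3-fold and Ier5l 11.7-fold. The ubiquitin ligase Rnf125 rose 10.7-fold, the linker histone H1f2 at least 9.64-fold and the interferon gamma receptor gene Ifngr1 9.25-fold. Pik3ip1 (11.2-fold) and Cwf19l2 (at least 11.0-fold) rose on suffixed probe sets. Of 5793 genes measured, 827 (14.3%) rose and 565 (9.75%) fell, 149 and 181 of them at least 4-fold, above every simulated value for arrays with no difference at both limits, also with this comparison's own spread (at most 1088 and 137).

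By list, immediate early factors fell in 16 of 21 cases and rose in 0 (median -2.76, percentile 0), with Jund (0.45) and, r-suffixed, Egr4 (0.36) at the other end. Cytokines fell in 12 of 14 cases and rose in 1 (median -3.84, percentile 0); Tnf rose 2.57-fold to 341, beside 334.5 with mock, and Ltb read -0.34. Of 26 anergy-linked genes 12 fell and 5 rose (median -0.82, percentile 0), Nedd4 (6.77-fold) and Rgs2 (4.90-fold) the most. Activation receptors fell in 4 of 12 cases, Tnfrsf9 at least 6.87-fold and Lag3 5.27-fold, and rose in 1, the inhibitory receptor Ctla4 (4.36-fold, from 373 to 1628; median -0.78, percentile 0.14). Effector genes fell in 4 of 7 cases and rose in 1 (median -1.995, percentile 0, range over the alternatives tried -2.01 to -0.93): Gzma fell 5.59-fold on an s-suffixed probe set and Il18rap 4.74-fold, and Stat4 rose 2.08-fold. Nucleolar genes fell in 8 of 20 cases and rose in 0 (median -0.97, percentile 0), Tsr1 5.04-fold and Nop58 5.43-fold (f-suffixed). Atf4 targets fell in 7 of 13 cases and rose in 0 (median -1.45, percentile 0.01), with Chac1 6.56-fold and Slc7a5 6.39-fold lower. Heat shock genes fell in 6 of 12 cases and rose in 0 (median -0.99, percentile 0.02), Hspa1b 7.50-fold.

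Glycolysis genes fell in 6 of 13 cases and rose in 2 (median -0.77, percentile 0.065), with Pfkp 4.81-fold (g-suffixed) and Tpi1 3.15-fold lower and Pdk1 3.95-fold higher. Sterol genes fell in 4 of 15 cases and rose in 1 (median -0.66, percentile 0.35); Idi1, an isoprenoid enzyme, fell 7.16-fold and Cyp51 at least 4.42-fold. MAP kinase phosphatases and Sprouty genes fell in 4 of 8 cases and rose in 2 (median -1.11, percentile 0.22), Dusp6 at least 12.4-fold (log2 ratio -3.63, and -1.69 on a second probe set). NF-kB genes fell in 3 of 14 cases and rose in 2 (median -0.47, percentile 1.5): Nfkbiz fell at least 7.39-fold and Bcl3 4.76-fold, while Tnfaip3 (A20), an inhibitor of NF-kB signalling, rose 2.96-fold and Birc2 2.16-fold. Interferon response genes rose in 4 of 7 cases, Tap1 2.97-fold and Psmb9 2.67-fold, and fell in 2, Irf8 12.6-fold and Gbp3 2.58-fold (median 1.10, percentile 99.455). Quiescence genes rose in 4 of 12 cases and fell in 0 (median 0.57, percentile 98.91), among them the translation inhibitor Pdcd4 (2.80-fold). In the receptor complex list 2 of 16 rose and 3 fell (median -0.47, percentile 1.94), with Lcp2 8.38-fold and Fyn 4.05-fold lower. Apoptosis regulators rose in 3 of 8 cases, Mcl1 2.68-fold (f-suffixed; 0.86 on a second probe set) and Xiap 2.12-fold, and fell in 1 (median 0.24, percentile 74.78). Reference genes read lower as well: housekeeping genes gave 0 up and 0 down of 9 (median -0.62, percentile 1.415) and ribosomal protein genes 0 up and 3 down of 26 (median -0.46, percentile 1.03), so the NF-kB and receptor complex medians lie no further out than these. The sterol median (-0.66) lies close to that of housekeeping genes. Over the alternatives tried, the housekeeping median ranged from -0.73 to -0.41. The ranges for sterol genes (-0.78 to -0.41), activation receptors (-0.91 to -0.46) and the Sprouty and phosphatase list (-1.63 to -0.51) overlap it.

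The fourth comparison, Combo with anti-TCR against anti-TCR alone, asks which changes need mTOR, MEK or p38, whose inhibitors were given together. Tnf rose 13.4-fold, from 133 to 1786, Ccl4 10.9-fold, from 237 to 2571 (both encode inflammatory mediators). Synrg rose at least 12.2-fold, Thap3 9.53-fold, H1f2 at least 7.98-fold, the sulfotransferase Chst12 5.35-fold and Adgrl3 5.24-fold; Cuta (at least 9.53-fold), Slco6b1 (6.33-fold) and Dusp28 (5.39-fold) rose on suffixed probe sets. Xcl1 fell 17.5-fold, Ccl9 at least 10.4-fold, Il5 at least 9.41-fold, the peroxiredoxin repair enzyme Srxn1 9.15-fold, Mmd 8.56-fold (second probe set only -0.72), Pou2f2, an octamer-binding factor, at least 7.77-fold, Pmepa1 7.64-fold, the RNA sensor Ifih1 7.42-fold and 1810035K13Rik at least 9.96-fold. Gchfr, 31.8-fold lower, was read on an r-suffixed probe set that gave 6187 to 8034 with mock and anti-TCR. The Egr family stayed high: Egr2 read 2116, Egr3 3470 and Egr1 639 (log2 ratios -0.65, -0.33 and 0.89), none past the size rule, although a second probe set of Egr3 gave -1.60, and Egr4 rose 2.05-fold on its r-suffixed probe set against -0.19 on the other. Of 5621 genes measured, 447 (7.95%) rose and 307 (5.46%) fell, 36 and 52 of them at least 4-fold; the sum at 2-fold, 754, lies within the first simulated range for arrays with no difference (705 to 858) and above the second (549 to 707), and the sum at 4-fold, 88, lies within both (highest 95 and 97). With this comparison's own, narrower spread noise gave at most 571 and 33. The excess of higher genes (59.3% of the changed ones) depends on the scaling, since with median scaling it was 49.5%.

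By list, cytokines fell in 8 of 14 cases and rose in 3 (median -1.72, percentile 0); Ccl1 fell 19.4-fold, while its second probe set gave 0.65. Immediate early factors fell in 3 of 21 cases and rose in 1 (median -0.58, percentile 0), with Fosb 3.42-fold and Fos 2.32-fold lower. Anergy-linked genes fell in 2 of 24 cases and rose in 0 (median -0.06, percentile 27.38), Nfatc1 2.73-fold with its 3 bright probe sets between -1.58 and 0.15, and the prostaglandin receptor Ptger2 2.24-fold; Bhlhe40 read 0.75. Activation receptors fell in 1 of 12 cases, Tnfrsf9 (2.67-fold), and rose in 0 (median -0.24, percentile 11.03). NF-kB genes rose in 3 of 15 cases, the adhesion molecule Icam1 4.18-fold and Tnfaip3 3.25-fold, and fell in 1, Nfkbiz (2.77-fold; median 0.12, percentile 72.355). Interferon response genes rose in 3 of 8 cases, Psmb9 3.48-fold and Irf1 3.14-fold, and fell in 1, Irf8 (2.70-fold; median 0.75, percentile 99.39). Nucleolar genes fell in 5 of 20 cases and rose in 0 (median -0.43, percentile 0.20), Gnl3 2.51-fold and Rrs1 2.50-fold. Atf4 targets fell in 4 of 13 cases and rose in 0 (median -0.55, percentile 0.505), with Chac1 2.81-fold lower. Sterol genes fell in 4 of 14 cases and rose in 0 (median -0.42, percentile 2.75), Idi1 4.40-fold and Cyp51 3.30-fold. In the effector list 2 of 7 fell and 1 rose (median -0.59, percentile 0.885): Gzma fell 5.16-fold (s-suffixed) and Gzmb 4.24-fold, to 477 beside 455 with mock. Housekeeping genes, a reference, read about as low as the sterol and nucleolar lists, with 0 up and 1 down of 9 (median -0.39, percentile 3.68). In the Sprouty and phosphatase list 1 of 7 fell, Spry1 (2.34-fold), and 1 rose, Dusp7 (2.69-fold; median -0.56, percentile 1.715).

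The 3 inhibitor arms were then compared over the 659 genes that anti-TCR raised, all of which share the same mock and anti-TCR arrays. CSA lowered 196 of them at least 2-fold (29.7%, Wilson 95% interval over genes 26.4% to 33.3%), PKCi 365 (55.4%, 51.6% to 59.1%) and Combo 208 (31.6%, 28.1% to 35.2%). With no inhibitor effect, 100 simulations gave 16.4%, 16.3% and 16.5% on average and at most 20.3%, 19.4% and 19.6%, or at most 26.4%, 26.7% and 26.7% with the wider spread of anti-TCR against mock, which for CSA lies within the Wilson interval. The median gene kept 66.9% of its log2 induction with CSA (63.1% to 70.8%), 28.7% with PKCi (22.9% to 34.2%) and 58.1% with Combo (55.1% to 61.3%); these intervals describe the number of genes only. Because the genes were chosen for a high anti-TCR value, the same simulations without inhibitor effect gave medians of 83.5%, 83.5% and 83.3% (lowest 79.5%, 79.9% and 80.1%), not 100%, and with the wider spread 76.7%, 76.5% and 76.7%. All these simulations started from the observed mock and anti-TCR values, which already hold noise. In this respect they understate the loss without inhibitor effect. The wider spread can hold real response, which acts the other way. PKCi alone left the least induction in 374 of the 659 genes, CSA in 130 and Combo in 139, with ties in 16. Examples chosen after their values were seen differ between arms. Lag3, the inhibitory receptor, kept 9.80% with CSA, 23.1% with PKCi and 95.6% with Combo, and Ndrg1 2.11%, 12.2% and 93.4%. Srxn1, whose mock value is below the floor, kept at least 95.1% with CSA, 17.1% with PKCi and 35.8% with Combo. Irf8 kept 92.3% with CSA, under 0% with PKCi, where it read 112 beside 148 with mock, and 55.9% with Combo.

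**Figure D3:**
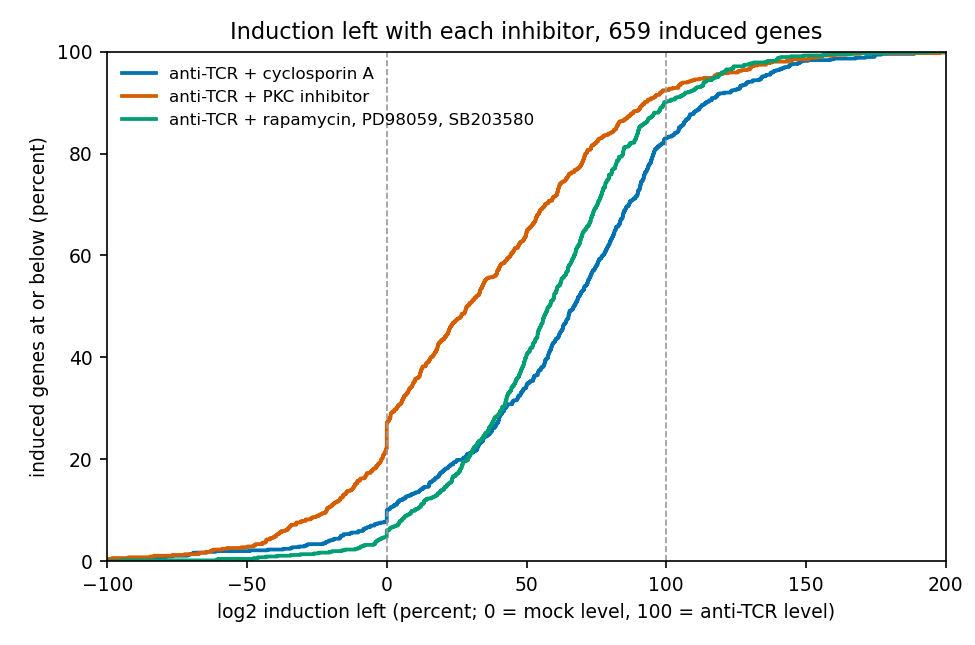
Cumulative share of the 659 induced genes (vertical axis, percent) by the share of the log2 induction left (horizontal axis, percent; 0 is the mock level and 100 the anti-TCR level), with 1 line per inhibitor arm. The PKCi line lies to the left, with a median of 28.7%, and the CSA and Combo lines have medians of 66.9% and 58.1%; steps at 0 are genes at the floor in both arrays.

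All 3 arms lowered 89 of the 659 genes at least 2-fold, PKCi alone 117, CSA and PKCi 72, PKCi and Combo 87, CSA and Combo 7, Combo alone 25, CSA alone 28, and none of the 3 lowered 234. The class lowered by CSA alone holds no more genes than noise without any inhibitor effect gave (55.6 and, with the second noise estimate, 41.8 on average). However, effects of the other arms take genes out of it, and both noise spreads (0.64 and 0.65) are wider than that of CSA (0.48). The count therefore cannot show whether the members of this class are noise, and they cannot be read as specific to calcineurin. Its 10 largest inductions were those of Nfkb2, the precursor of an NF-kB subunit (5.52-fold up, then 2.32-fold down with CSA), the amino acid transporter chain Slc3a2 (4.37-fold, then 2.15-fold), Nfkbib (3.77-fold, then 2.26-fold), the GTPase Gimap1 (4.15-fold, then 2.12-fold), Aifm3 (4.77-fold, then 6.07-fold), the histone demethylase Kdm2b (3.86-fold, then 4.09-fold), Nle1, Thoc3, Srp68 and Srgap1. Most of these CSA changes lie near 2-fold, where single arrays do not separate a change from noise.

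Changes against anti-TCR alone were also compared between arms. Among 5255 genes measured in both, CSA and PKCi shared 195 lower and 154 higher genes, against 31.3 and 22.1 for independent lists and 151 and 103 (at most 187 and 126) in simulations where only the anti-TCR array was shared. PKCi and Combo shared 211 lower and 306 higher genes of 5433, against 31.9 and 47.0 for independent lists and 152 and 102 (at most 186 and 123) simulated. CSA and Combo shared 109 lower and 89 higher genes of 5211, against 17.1 and 10.8 for independent lists and 152 and 102 simulated. The covariance of the log2 ratios was 0.457, 0.525 and 0.269 for these pairs against 0.259, 0.259 and 0.259 simulated, differences of 0.198, 0.266 and 0.00953. The simulations used the pooled spread (0.64), which is wider than that of CSA (0.48) and Combo (0.55) and narrower than that of PKCi (0.71). For CSA and Combo the simulated overlap and covariance may therefore be too high, so they do not show that these arms share no response. With 1 anti-TCR array the controls cannot be split, so part of each overlap may come from that shared array. A separate selection of 208 genes, induced at least 2-fold on 1 probe set and read on another probe set on another chip type, gave a smaller median log2 ratio of anti-TCR to mock (0.45, 95% interval 0.32 to 0.59, against 1.65 on the probe set that chose them), and ratios to anti-TCR alone of -0.46 with PKCi (-0.54 to -0.32), -0.28 with Combo (-0.36 to -0.21) and -0.16 with CSA (-0.23 to -0.09). Across 6337 genes, which are not independent replicates, the Pearson correlation between arrays was lowest for mock and anti-TCR (0.664) and highest for mock and PKCi (0.853). Close behind were anti-TCR and CSA (0.848), CSA and Combo (0.847) and PKCi and Combo (0.845).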

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

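All tests in this part were chosen after the result was seen. Probe sets without a single gene name lie outside the gene counts and were looked at because some of them differed strongly between anti-TCR and mock. Of 1409 that reached 4 times the floor with mock or anti-TCR, 136 were at least 2-fold higher and 143 at least 2-fold lower with anti-TCR. The sum, 279 (19.8%), lies above what 100 simulations without difference gave with the first 2 noise estimates (at most 244 and 206). With the spread of this comparison alone they gave 307 to 380. The observed sum lies below that whole range, so this spread is too wide for these probe sets and cannot decide. Whether the sum at 2-fold stands apart from noise depends on the estimate. At 4-fold, 64 lay apart, against at most 39, 31 and 61. The largest rise was on chip type B, probe set 116393_at, from 22.7 to 3261 (at least 46.9-fold), with 1148 under CSA, 26.7 under PKCi and 1283 under Combo. The next was on chip type A, probe set 97519_at, from 122.5 to 3175 (25.9-fold), with 2859 under CSA, 92.4 under PKCi and 2409 under Combo. Both read near mock with PKCi, like Egr2 and Egr3. No biological explanation was tested.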

How the results depend on the processing

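The settings that leave out suffixed probe sets or require agreement of probe sets were chosen after the data were seen. The limits for a change were 1.5 times for counts, the 95% interval for percentages and medians, and the technical SD for single genes. Of the counts, percentages and medians, 99 stayed within the limits set for a change and 33 did not. Of single-gene values 3054 stayed, 87 moved and 2 reversed. All 675 list medians stayed, but within intervals so wide for short lists that a median could change sign. Examples of ranges over the settings are activation receptors with anti-TCR (0.72, range 0.60 to 1.20) and housekeeping genes with anti-TCR (0.24, -0.25 to 0.29). Others are apoptosis regulators with Combo (-0.47, -0.53 to 0.58) and MAP kinase phosphatases and Sprouty genes with CSA (-0.08, -1.10 to 0.04). The calcineurin and NFAT list with PKCi (0.47) ranged from -0.08 to 0.49. With 2 times the floor, and equally with 8 times the floor as minimum, fewer genes pass: 468 were lower with anti-TCR than mock, 138 higher and 193 lower with CSA, 467 and 371 with PKCi, and 228 and 197 with Combo, and PKCi lowered 59.3% of induced genes. With 0.5 times the floor more genes pass: 467 were higher with CSA, 739 higher and 499 lower with Combo, PKCi lowered 51.4% of induced genes, and its median share left was 0.343. With median scaling 49.7% of the genes changed with anti-TCR and 49.5% with Combo were higher (44.9% and 59.3% as reported), and the median share left with Combo was 0.546; the cause was not tested. Counted as under 50% of the log2 induction left, CSA lowered 34.4%, PKCi 64.6% and Combo 40.5% of induced genes. Genes with 2 or more bright probe sets, all at least 2-fold apart, are fewer by construction: 81 higher and 61 lower with anti-TCR, 23 and 35 with CSA, 68 and 71 with PKCi, and 16 and 20 with Combo. Without suffixed probe sets Egr4 is read on another probe set and its log2 ratio to anti-TCR alone reversed, to -0.0058 with CSA and -0.19 with Combo. The planned floor from bacterial control probe sets was not run, since the tables used hold 0 of them. Leaving out a replicate is impossible with 1 array per treatment and chip type. Signal over background limits the comparisons to the 17.4% to 23.0% of probe sets that reach 4 times the floor.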

Other observations

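Chosen after the results were seen were the counts of genes beyond both mock and anti-TCR, the test of whether the PKCi arrays hold the labelled mock RNA, the test of a low anti-TCR reading for Tnf and Ccl4, the simulation with the wider spread, and the reading of the Combo value against -0.1. Some genes lay at least 4-fold beyond both mock and anti-TCR alone in an inhibitor arm, and those named were picked after their values were seen. Ier5l, of an immediate early family, read 338 with mock and 264.5 with anti-TCR but 5812 with CSA, 3103 with PKCi and 412 with Combo, and a second probe set rose too (log2 ratio to anti-TCR alone 3.40 with CSA and 1.804 with PKCi). Crem, a cAMP-responsive repressor, read 76.7, 252, 723, 1139 and 315 in the order mock, anti-TCR, CSA, PKCi and Combo (s-suffixed; second probe set also higher). Ddit4, a stress-induced inhibitor of mTOR, read 415, 301, 1250, 1727 and 346, and the repressor Scrt1 164, 164, 746, 994 and 433. Icam1, an adhesion molecule, read 33.1, 58.4, 31.0, 35.2 and 244, and reached 4 times the floor only with Combo, and Jund, an AP-1 subunit, read 780, 635, 149, 867 and 1205, lowest with CSA. In all, 6 genes lay higher and 7 lower with CSA, 14 and 12 with PKCi and 4 and 5 with Combo, which the pooled noise estimate can give (at most 26 and 14).

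Genes that anti-TCR raised read lower in all 3 inhibitor arms, and the simulations alone cannot decide whether noise in the shared anti-TCR array gave this. For each inhibitor the observed share lowered lay above the highest of 100 simulations. The smallest gap was 9.401 percentage points with the pooled spread. With the wider spread of anti-TCR against mock it was 3.32, within the interval of the share for CSA. For PKCi the share lowered was 55.4%, against at most 26.7% with the wider spread. However, the simulations started from the observed mock and anti-TCR values, which already hold noise. In this respect they understate the loss that noise alone gives. The wider spread can hold real response, which acts the other way. On other probe sets the induction of a separate selection was 0.45, against 1.65 on the choosing ones. Noise of the choosing probe sets, which by the bound set in advance leaves a median log2 ratio of -0.1 or higher on other probe sets, is argued against for PKCi (-0.462) and Combo (-0.276), whose intervals lie below it. It stays open for CSA (-0.162, interval -0.23 to -0.09, which excludes 0 but reaches -0.1). The second bound set in advance, an interval below -0.3, was met by PKCi alone and was strict, since the induction itself was 0.45 on these probe sets. The other probe sets lie on another chip type, and so on another anti-TCR array. For PKCi the ratio on them therefore also argues against noise of the choosing anti-TCR array, for the 208 genes read. A difference between the single cultures or RNA preparations behind each pool stays open for all 3, since no array repeats a treatment.

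The PKCi arm lies close to mock. Between PKCi and mock 592 genes lay 2-fold and 85 lay 4-fold apart, where pooled noise gave 705 to 858 and 51 to 95. The 592 lies below that range, so the pooled spread is too wide for this pair. It cannot show whether the differences between PKCi and mock are noise. A low count is not particular to this pair. At 2-fold PKCi and Combo (497), anti-TCR and CSA (555) and CSA and Combo (591) lay closer, although 85 was the lowest 4-fold count of the 10 pairs. If the PKCi arrays held the labelled RNA of the mock arrays, log2 ratios of PKCi to mock would share nothing between probe sets of the same gene on different chip types. Their r across genes was 0.261 (95% interval 0.184 to 0.334, and 0.256 with a trend by level removed), the lowest of the 10 pairs of treatments, which argues against that RNA alone. An even dilution of the whole response is argued against as well: among 228 genes induced at least 4-fold the interquartile range of the share left exceeded the highest of 100 simulations by 0.178. A second labelling of mock RNA, another culture that was not stimulated, loss of cells and a toxic effect were not tested and stay open.

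Tnf and Ccl4 read higher with CSA and with Combo than with anti-TCR alone. A low reading on the anti-TCR array and a faulty probe set cannot be told apart from a real rise for either gene, since 0 further probe sets reached 4 times the floor. No biological explanation was tested.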
